A study of Mus musculus with 4 samples.

How the data were processed

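Chromatin accessibility was measured by single-cell ATAC-seq, in which a transposase cuts and tags open DNA inside nuclei, in sorted CD4-negative CD8-negative (double-negative) mouse thymocytes of the C57BL/6J strain. Per the labels there were 4 libraries, 2 from wild-type (WT) mice and 2 from mice of the ΔEPE3 genotype, made with a droplet kit for single nuclei and sequenced on an Illumina NovaSeq. The labels do not say whether the libraries of a genotype came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical.

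For each library the deposited files used here were a list of peak positions and a raw list of cell barcodes. Per the submitters' processing notes, the build was mm10 and the tools named were Cell Ranger ATAC and Cell Ranger, with no version, Seurat 3 and Signac 0.2.1. Their settings are not given in the sources used here. The peak lists hold positions only, with no height, score or count, and the 4 lists differ in number and in peak ends, so that peaks were called in each library on its own. Count matrices were not analysed here. Sequencing depth and the number of cells per library are therefore unknown, and a library with more fragments can list more peaks with no difference in chromatin. No interval for counting error can be given. No values per cell were used, so doublets (droplets with more than 1 nucleus) were neither called nor removed, and whether the submitters did so before calling peaks is not given in the sources used here. A raw barcode list holds empty droplets as well as cells, and was used only to compare the lists.

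Peaks on chromosomes 1 to 19, X and Y were kept. One line of the list of WT 2 was empty, and peaks in the stretch around it were left out in every library. Peaks of the 4 libraries that overlapped by at least 1 bp were merged into union regions, and a region counted as called in a library when a peak of that library lay in it. Regions called in both libraries of 1 genotype and neither of the other are named WT-only and ΔEPE3-only. Called length is the number of bases inside peaks. Gene positions came from a RefSeq table of GRCm38.p6, which has the coordinates of mm10. It carries no strand and came with no genome sequence. The planned promoter class was therefore replaced by the regions within 1 kb of either end of a protein-coding gene, the planned distance to the nearest transcription start by the distance to the nearest gene body, and the planned motif search was not run. A region was assigned to each protein-coding gene whose body, extended by 10 kb on either side, it touched.

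Peak numbers, called length and peak width were compared by an exact two-sided permutation test, for which 2 libraries against 2 cannot give a p below 0.33. Peak lists were compared by the Jaccard index of called bases. Regions specific to a genotype were counted and set beside the counts for the other 2 ways to split the 4 libraries in pairs. Fisher's exact tests of annotation are across regions, which are not replicates. Called length per gene (body extended by 10 kb) and per 100 kb window was tested with limma 3.58.1 in R 4.3.3, with trended and robust empirical Bayes, on log2(called bases + 500), each library centred on its median, in features with called bases in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are ΔEPE3 minus WT on that scale, relative to the median gene, and understate changes of features with few called bases. A total of 13 gene lists, 231 entries in all and 218 different genes, all matched in the table, were tested with camera at its preset correlation, with an estimated correlation, and with fry. WT-only minus ΔEPE3-only regions at each list were placed among 10000 random gene lists matched on the number of union regions per gene. This percentile describes these libraries and is not a test over replicates. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

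Runs of neighbouring regions around Tcf7 and the receptor loci were drawn at random from the rest of the genome, 10000 per locus, a test added after the data were seen. The principal components, the limma fits to the other splits of the libraries and the list percentiles of single region classes were also not planned. These classes are WT-only regions, ΔEPE3-only regions and regions of pairs that mix genotypes. The design, the other tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Further exceptions are stated where they occur. The rule names Tcf7, the 3 genes of each list with the largest difference between WT-only and ΔEPE3-only regions, the 5 genes genome-wide with the most and the 5 with the fewest WT-only minus ΔEPE3-only regions, and the leading limma calls in each direction, of which there were none. Ties went to the larger fitted log2 difference. Genes named by that rule were picked for their size and lie at the extreme for that reason. The alternatives were other minimum overlaps, merging of peaks up to 500 bp apart, equal numbers of the widest peaks, autosomes only, other scalings, pseudocounts, filters and gene windows, peak numbers in place of lengths, replicate blocks and leaving out each library.

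The limma step was tested on simulated data, and what it recovered depended on how the calls were simulated. The simulation run first drew the calls of a gene's regions with 1 shared probability and planted 2-fold and 4-fold changes alone. It recovered 0 of 100 genes at 2-fold and 0 of 100 at 4-fold. The step itself was not altered after that. With 8-fold changes planted as well, the same model gave 0 of 100 at 2-fold, 24 of 100 at 4-fold and 40 of 100 at 8-fold. A second model, in which each region kept its own share of calls, gave 21, 58 and 82 of 100. Folds planted in the real values, in genes with long called length in every library, were recovered in 0 of 200 genes at 2-fold, 178 of 200 at 4-fold and 200 of 200 at 8-fold. Those 200 genes were changed together in 1 run per fold. Recovery with fewer changed genes, which the adjustment over all genes can lower, was not tested. At most 1 gene with no planted change was called in a run. All planted changes were losses of called length in ΔEPE3, and the recovery of gains was not tested. A count of 0 genes in the comparison of called length per gene therefore leaves room for 2-fold losses and for many 4-fold ones. Under both models of simulated calls, with 40 and 82 of 100 recovered, it leaves room for some 8-fold losses as well. For gains no such limit is known. In the test of lists by region, 0 of 13 lists left the random range with no change planted, and a list given 1 extra region per gene reached the top percentile of 100.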

Results

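The series asks, per its title, how the dosage of TCF1 shapes cell fate in T cell development. TCF1 is the transcription factor encoded by Tcf7 that acts early in the T lineage. Chromatin accessibility was compared between WT and ΔEPE3 double-negative thymocytes, immature thymic cells that carry neither CD4 nor CD8. The position of EPE3 is not given in the sources used here, so the deletion could not be used to check the labels. The lists of WT 1 and WT 2 gave 153030 and 161655 peaks for analysis, and those of ΔEPE3 1 and ΔEPE3 2 gave 176781 and 171960. The depth behind these lists is unknown. The raw barcode lists held 594472, 543011, 566167 and 568055 barcodes in the same order, which do not count cells.

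The chromatin around Tcf7 (gene 21414, chromosome 11, 52246527 to 52283383, mm10) was largely open in the same places in both genotypes. Of 63 union regions within 100 kb of the gene, 43 were called in all 4 libraries, and the libraries called 47, 52, 54 and 49 of them (WT 49.5 ± 3.54, ΔEPE3 51.5 ± 3.54, SD, n = 2). On the side of higher coordinates, 24 of 28 regions were called in all 4 libraries and 0 were WT-only. The shares were lower inside the gene, at 8 of 13, and on the side of lower coordinates, at 11 of 22. The single WT-only region lay at 52186770 to 52187832, outside protein-coding genes and 58695 bp from the low-coordinate end of Tcf7, with 841 called bases in WT 1 and 997 in WT 2. Genome-wide shares would give 0.576 WT-only regions there, so 1 region does not stand out, and no region is taken here to be the deleted element. The ΔEPE3-only regions numbered 3, against 3.02 from genome-wide shares, and lay at 52239265 to 52240023 in Skp1, at 52249078 to 52250022 inside Tcf7 and at 52370325 to 52371232 in Vdac1. Within 1 Mb of the gene, a window chosen after the data were seen, 29 of 379 regions were ΔEPE3-only and 3 WT-only, against 18.2 and 3.46 from genome-wide shares, at percentiles 97.8 and 47.9 among 10000 runs of as many neighbouring regions. Called length over Tcf7 and its 10 kb flanks was 11.3 ± 0.603 kb in WT and 12.1 ± 0.589 kb in ΔEPE3 (SD, n = 2), a log2 difference of -0.05 ± 0.11 (SE) relative to the median gene with a limma adjusted p of 0.942. The WT-only count at the locus moved to between 1 and 5 when single libraries were left out, by which a region needs fewer libraries.

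**Figure D1:**
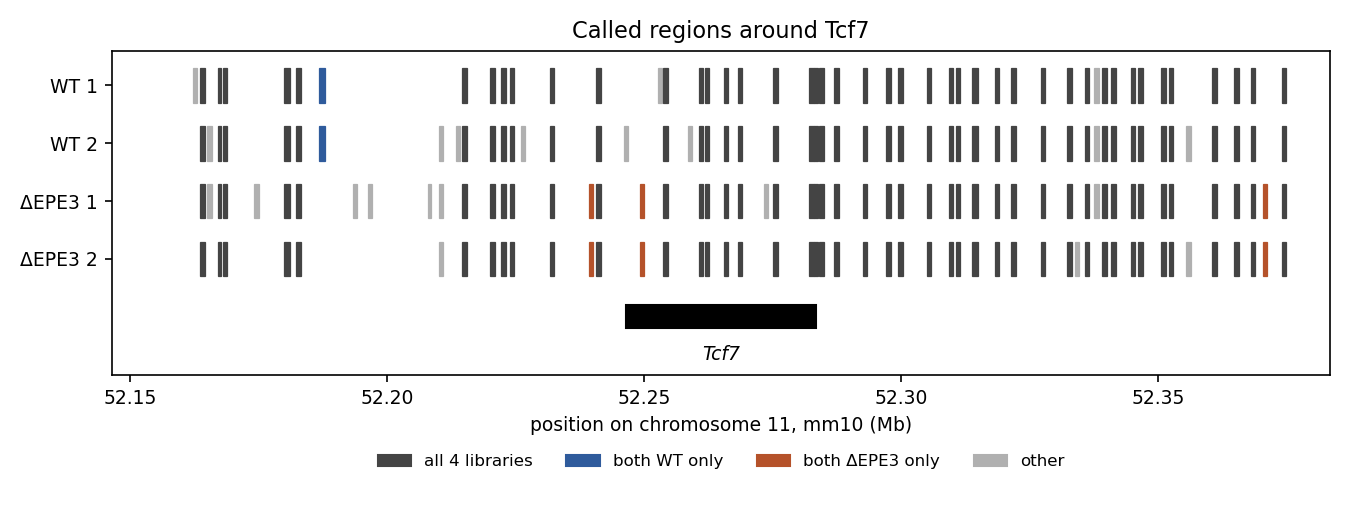
Called regions within 100 kb of Tcf7 in each library, by position on chromosome 11 (mm10, Mb); each bar spans a union region in a library that called it, dark bars mark the 43 regions called in all 4 libraries, blue the 1 WT-only region, red the 3 ΔEPE3-only regions and light grey the others. The black box is the Tcf7 gene body.

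Across the genome, ΔEPE3 cells had more called regions than WT cells. Peaks numbered 174370.5 ± 3409 in ΔEPE3 and 157342.5 ± 6099 in WT (SD, n = 2), 10.8% more, with both ΔEPE3 libraries above both WT libraries (exact permutation test, two-sided p = 0.33, the smallest this design allows). Called length was 147.3 ± 2.77 Mb against 132.3 ± 5.02 Mb (SD, n = 2). Merging gave 236598 regions, of which 107150 (45.3%) were called in all 4 libraries and 59868 in 1 library. ΔEPE3-only regions numbered 11359 and WT-only regions 2162. With equal numbers of the widest peaks they numbered 8809 and 6826, a ratio of 1.29 in place of 5.25. With 1 library left out, ΔEPE3-only and WT-only regions numbered 15216 and 15603 without WT 1, and 27367 and 14782 without WT 2. They numbered 22683 and 6412 without ΔEPE3 1, and 33842 and 9858 without ΔEPE3 2. Each of these asks for 2 libraries of 1 genotype and 1 of the other. The counts of the 2 genotypes then follow unlike rules, so their order is no check on the excess. Between single libraries, 1 of each genotype, the regions found in ΔEPE3 alone were 1.38 to 1.86 times those found in WT alone over the 4 pairs. That direction follows from the longer ΔEPE3 lists. Part of such an excess can follow from depth, which is unknown.

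A larger division of the libraries did not follow genotype. WT 1 and ΔEPE3 2 shared 11288 regions absent from the others, and WT 2 and ΔEPE3 1 shared 7644, together 18932 against 13521 for the split by genotype. The remaining split, by replicate number, gave 3027 and 2289. The mean Jaccard index was 0.610 for the 2 pairs within a genotype and 0.606 for the 4 pairs between genotypes. WT 1 with ΔEPE3 1 was at 0.528, and the other pairs between genotypes ran from 0.630 to 0.634. The lists were thus no more alike within a genotype. For called length per gene, the axis of largest variation (first principal component, 52.0% of variance) ran WT 1, ΔEPE3 2, WT 2, ΔEPE3 1. The second (25.9%) set the genotypes apart, with WT at -6.18 and -29.0 and ΔEPE3 at 10.8 and 24.3. Within the pairs that shared most, ΔEPE3 2 listed 12.4% more peaks than WT 1, and ΔEPE3 1 listed 9.36% more than WT 2. Both ΔEPE3 lists were longer than both WT lists, so an excess in each pair follows from the totals and is no separate check.

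**Figure D2:**
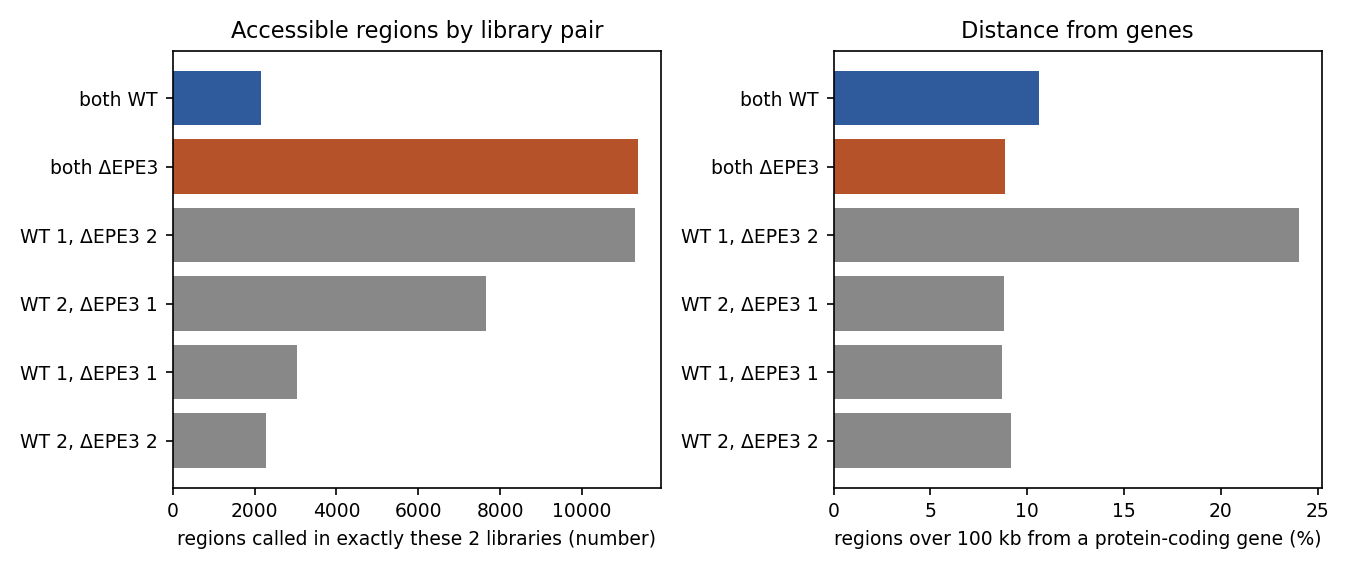
Left, the number of union regions called in exactly the 2 libraries named; right, the percentage of them more than 100 kb from any protein-coding gene. Blue is WT-only (2162 regions), red is ΔEPE3-only (11359) and grey marks pairs that mix genotypes; the regions of WT 1 with ΔEPE3 2 stand apart at 24.0%.

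Regions missing from some libraries lay at gene ends less often than those called in all 4, whether or not they followed genotype. Of the regions called in all 4 libraries, 16.7% lay within 1 kb of an end of a protein-coding gene, against 6.75% of WT-only and 5.54% of ΔEPE3-only regions. The 4 pairs that mix genotypes had 4.23% to 7.21%, and regions called in 1 library 4.91%. In all 4 libraries, WT-only and ΔEPE3-only, the shares inside gene bodies were 46.2%, 52.0% and 53.0%, and those in intergenic space 37.1%, 41.3% and 41.4%. ΔEPE3-only and WT-only regions differed by -1.22 percentage points at gene ends (Fisher's exact test across regions, adjusted p = 0.0358 over 12 tests). Without WT 1 that difference was 0.886 points, and without WT 2 it was 0.840. In these settings WT-only regions take in those called in 1 WT library alone. Of such regions, 4.81% (WT 1 alone) and 4.85% (WT 2 alone) lay at gene ends. The change of sign can therefore follow from the looser definition. The difference was -0.233 without ΔEPE3 2 and -2.82 without ΔEPE3 1. With equal numbers of the widest peaks it was -10.2 points, a setting in which WT 1 keeps all its peaks, short ones included.

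At genes of T lineage specification, the excess of ΔEPE3-only regions was inside the range of matched random lists with all 4 libraries. At the 30 genes of this list, 396 of 723 regions were called in all 4 libraries, 41 were ΔEPE3-only and 9 WT-only, at percentile 24.7 among matched random lists. That place was not stable, from 2.02, outside the range, without WT 1 to 83.1 without ΔEPE3 1, and 93.7 with equal numbers of the widest peaks. Ranges of percentiles for the other lists are over the 4 settings with 1 library left out. ΔEPE3-only regions outnumbered WT-only regions at 12 genes and the reverse held at 1. Tox, a nuclear factor of T cell development (chromosome 4, 6686353 to 6991557), had 11 ΔEPE3-only and 1 WT-only regions, with 49.0 ± 6.12 kb called in ΔEPE3 and 35.7 ± 1.23 kb in WT (SD, n = 2). Tcf12, which encodes the E protein HEB (chromosome 9, 71844252 to 72111893), had 10 and 1, and Themis, a T cell signalling gene, had 3 and 0. Their log2 differences were 0.30 ± 0.11, 0.28 ± 0.11 and 0.13 ± 0.12 (SE), with limma adjusted p values of 0.878, 0.878 and 0.891. With 1 library left out they ran from 0.181 to 0.410, from 0.164 to 0.398 and from 0.0171 to 0.232, each lowest without ΔEPE3 1 and highest without ΔEPE3 2. The regions of this list were also unevenly spread over the mixed pairs, with 6 in WT 1 and ΔEPE3 2 only and 27 in WT 2 and ΔEPE3 1 only. At the 15 genes of T cell receptor and Notch signalling there were 14 ΔEPE3-only and 1 WT-only regions (percentile 22.8, range 2.23 without WT 1 to 74.7 without ΔEPE3 1). Nfatc2 had 4 of 41 regions, Bcl2 3 of 58, near the genome-wide share, and the receptor gene Notch1 2 of 19, each with 0 WT-only. Double-positive genes, of the next thymic stage, had 7 and 2 (percentile 85.0, range 50.6 to 92.8), with Arpp21 at 3 and 0 of 52 regions. Gamma delta T cell genes had 12 and 1 (percentile 31.4, range 3.76 without WT 2 to 93.0 without ΔEPE3 2). Etv5 had 3 of 19 regions, Il23r 3 of 29 and Sox13 2 of 18.

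Of the lists for other lineages, 1 lay outside the random range, and which one depended on the setting. Dendritic cell genes had 6 ΔEPE3-only and 5 WT-only regions, at percentile 98.5, which is relatively more WT-only regions than in matched lists. Tcf4, the E protein gene of plasmacytoid dendritic cells, had 2 WT-only and 0 ΔEPE3-only, Irf8 1 and 0, and Zbtb46 0 and 1. With 13 lists examined, 1 outside a 95% range is near what chance gives, and this list returned inside the range without any 1 of the 4 libraries, at percentiles from 25.3 to 96.9, and with an overlap of at least 50% of the shorter peak, at 97.0. It stayed outside with equal numbers of the widest peaks (99.4) and with the nearest gene (99.7). Innate lymphoid and NK cell genes had 10 ΔEPE3-only and 7 WT-only regions (percentile 95.6). With the 50% overlap they were at 97.9, which is outside the random range. Without WT 2 they were at 1.51, outside the range on the opposite side, and the range ran to 74.3 without ΔEPE3 2. Counted alone, the 7 WT-only regions lay at percentile 99.3. Of these, 4 lay at 1 gene, Rora, which had 103 regions and 2 ΔEPE3-only, so the count rests largely on that gene. The genes of this list also had 17 regions in WT 2 and ΔEPE3 1 only, against a median of 8 in matched lists. They had 8 in WT 1 and ΔEPE3 2 only. In this list Il1rl1, the interleukin 33 receptor gene (chromosome 1, 40404864 to 40465418), had 4 ΔEPE3-only and 1 WT-only, Il18rap 2 and 0, and Il2rb 0 and 2. Multipotent progenitor genes had 20 and 1 (percentile 15.1, range 11.3 to 31.0). Erg had 5 and 1 of 65 regions, Bcl11a 3 and 0 of 31 and the stem cell factor receptor gene Kit 3 and 0 of 28. Myeloid genes had 10 and 2 (percentile 20.3, range 3.13 without WT 2 to 90.7 without ΔEPE3 2), with Lyz2, Mpo and Itgam at 2 and 0 each. B cell genes had 11 and 2 (percentile 44.0, range 28.7 to 79.2). Btk had 3 and 0 of 13 regions, Pax5 2 and 0 of 24, and Ebf1 3 and 1 of 65. Erythroid and mast cell genes had 6 and 0 (percentile 5.27, range 2.78 to 7.76, and 0.575 with regions assigned to the nearest gene), with the mast cell protease gene Cpa3 at 3 and 0. Thymic stroma had 6 and 1 (percentile 50.0, range 9.02 without WT 2 to 82.9 without ΔEPE3 2), cell cycle 8 and 1 (percentile 41.2, range 27.5 to 55.4) and housekeeping genes 4 and 0 (percentile 52.3, range 26.0 to 75.4). At 10 of 13 lists both ΔEPE3 libraries called a larger share of the regions than both WT libraries. Chance gives that order in 16.7% of cases only among libraries with no general difference, and it also held genome-wide. It can follow from the longer ΔEPE3 peak lists, at gene lists that share the same 4 libraries, and is no separate check on these genes.

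**Figure D3:**
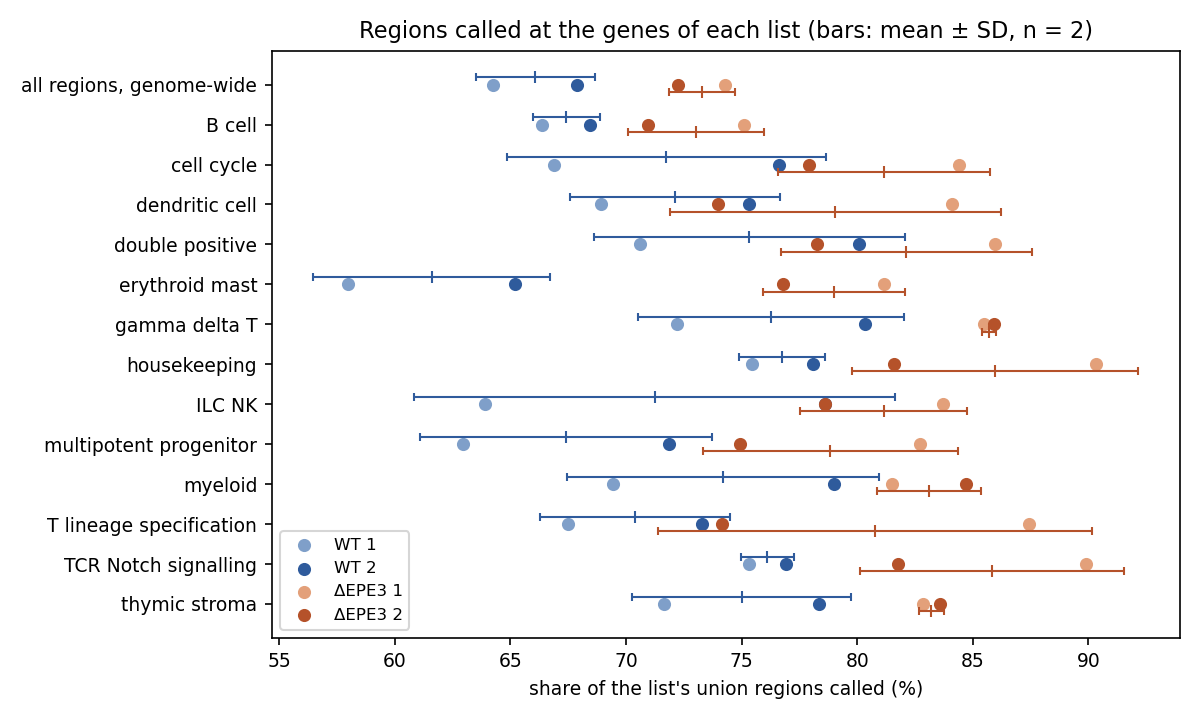
Share of each list's union regions called in each library (points, %), with the mean ± SD of each genotype (bars, n = 2); the axis starts above 0. The top line gives all regions genome-wide, at 64.3% and 67.9% in WT and 74.3% and 72.3% in ΔEPE3, and most lists show the same order.

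None of the 13 lists passed the test on called length with limma and camera (smallest adjusted p 0.976), with an estimated correlation (smallest adjusted p = 0.977) or with fry (0.542). The number of members past the threshold was 0 in each list, over all genes and adjusted over the list alone. Among list members, Il1rl1 had 11.6 ± 1.06 kb called in ΔEPE3 and 6.07 ± 1.54 kb in WT (SD, n = 2), a log2 difference of 0.74 ± 0.17 (SE; limma adjusted p = 0.878, and 0.0494 without ΔEPE3 2), and Cpa3 a log2 difference of 0.70 ± 0.23 (SE; limma adjusted p = 0.878). With 1 library left out, these ran from 0.563 to 0.921 and from 0.392 to 0.997, each lowest without WT 1 and highest without WT 2.

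Genome-wide, the genes with the largest excess of WT-only regions were Gtdc1 (chromosome 2, 44564412 to 44927717) with 4 and 0, and Dtd1 (chromosome 2, 144599953 to 144768747), Zfp978, Epb41l2 and Dapk1 with 3 and 0 each. Gtdc1 had 20.5 ± 1.20 kb called in WT and 12.1 ± 1.72 kb in ΔEPE3 (SD, n = 2), a log2 difference of -0.89 ± 0.15 (SE), and Dtd1 had 15.8 ± 1.20 kb and 9.48 ± 1.28 kb, a log2 difference of -0.86 ± 0.14 (SE). Those with the largest excess of ΔEPE3-only regions were long genes with many regions. Wwox had 15 and 0 of 193, Sox5 12 and 0 of 167, Prkce 12 and 0 of 93, Rptor 11 and 0 of 77, and Bcas3 11 and 0 of 92. Rptor, which encodes a subunit of the growth regulator mTORC1 (chromosome 11, 119602905 to 119899591), had 50.7 ± 1.73 kb in ΔEPE3 and 32.8 ± 3.19 kb in WT, a log2 difference of 0.48 ± 0.08 (SE). The limma adjusted p of each was 0.878. Without ΔEPE3 1 the limma adjusted p was 0.00203 for Gtdc1 and 0.0388 for Zfp978, and without ΔEPE3 2 it was 0.00899 for Gtdc1, 9.2e-04 for Dtd1, 0.00239 for Sox5, 0.029 for Bcas3 and 0.0333 for Rptor. Without WT 1 or WT 2 none of these genes passed, and Gtdc1, Dtd1 and Rptor were at 0.854 and 0.602.

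Over all genes, 0 of 18718 passed with limma (smallest adjusted p 0.878), and 985 had an unadjusted p under 0.05 where chance gives 936. Of 20857 windows of 100 kb, 0 passed (smallest adjusted p 0.930) and 911 had an unadjusted p under 0.05 where chance gives 1043. The counts rose to 19 genes without ΔEPE3 1, and to 405 genes and 1569 windows without ΔEPE3 2, fits in which the lone ΔEPE3 library is assumed to vary like WT. The same model called 8 genes and 1864 windows for the split of WT 1 and ΔEPE3 2 from WT 2 and ΔEPE3 1, and 0 of either for the split by replicate number.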

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

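All tests in this part were chosen after the result was seen. Antigen receptor segments are not protein-coding genes in the annotation and were outside the comparisons above, so 7 receptor loci were examined. At Tcra (chromosome 14, 52427967 to 54224198, a span that contains Tcrd), ΔEPE3-only minus WT-only regions came to 33, from 34 and 1 of 322 regions, and both ΔEPE3 libraries stood above both WT libraries. The libraries called 209 and 239 regions in WT and 293 and 260 in ΔEPE3. Relative to each library's genome-wide share of called regions, these were 1.01 and 1.09 in WT and 1.22 and 1.12 in ΔEPE3. On that scale WT 2 and ΔEPE3 2 were close. Of the 34, 29 lay across the Trav segments, where 258 regions were found, and 0 in the span of Traj segments and Trac. Tcrb gave the opposite sign, with 1 ΔEPE3-only and 3 WT-only of 118 regions (percentile 1.11 among runs of as many neighbouring regions, adjusted p 0.0788), which did not hold without ΔEPE3 2 (10 more ΔEPE3-only than WT-only, percentile 34.3); it was at 26.1 without WT 1, 3.17 without WT 2 and 0.79 without ΔEPE3 1. Tcrg, Tcrd, Igh, Igk and Igl lay at percentiles 31.3, 91.8, 8.29, 11.1 and 43.0.

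A general gain of peaks in ΔEPE3 would give about 13 at Tcra, the median of 10000 runs of 322 neighbouring regions elsewhere, and 33 lay at percentile 99.99 (empirical two-sided adjusted p 0.0028 over the 7 loci). With single libraries left out the percentile was between 97.8 and 99.98, but the adjusted p over the 7 loci stayed under 0.05 only without WT 1 (0.0049), at 0.0735 without WT 2, 0.119 without ΔEPE3 1 and 0.212 without ΔEPE3 2. Neighbouring regions are not replicates, and the libraries remain 2 per genotype. A larger share of cells near the double-positive stage, in which Tcra opens, may add such regions, although the sort for cells without CD4 and CD8 would remove most of them. The double-positive list had fewer ΔEPE3-only regions than most matched lists (percentile 13.8), a value inside the random range, and many of its regions were already called in all libraries, so that this stays open. An effect of the ΔEPE3 genotype on the locus was not tested apart from these.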

How the results depend on the processing

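Peak numbers and overlap of lists moved by less than the spread between libraries or pairs; the mean Jaccard index within minus between genotypes was 0.00407, and 0.0137 with equal numbers of the widest peaks (SD between pairs 0.052). Equal numbers of peaks fix the ratio of peak numbers and give no value there. Leaving out a library loosens what counts as specific to a genotype, so counts rise by construction. WT-only regions ran from 6412 to 15603 and ΔEPE3-only from 15216 to 33842. ΔEPE3-only regions were the more numerous in 3 of the 4 settings, and WT-only regions without WT 1 (15216 and 15603). A region then needs 1 library of 1 genotype but 2 of the other, so this order is no check on the excess. With equal numbers of the widest peaks WT-only regions were 6826, the WT-only count at Tcf7 was 4, the difference at gene ends -10.2 points and the intergenic difference 5.90 points. The WT-only count at Tcf7 ran from 1 to 5 with single libraries left out, and was 3 with 1 Mb either side, chosen after seeing the data. The difference at gene ends was -0.531 points with a 500 bp window and ran from -2.82 to 0.886 with libraries left out. It changed sign without WT 1 (0.886) and WT 2 (0.840), where WT-only regions take in those called in 1 WT library alone. The intergenic difference, 0.189 points with all libraries, ran from -8.63 without ΔEPE3 2 to 4.59 without ΔEPE3 1, and was -1.96 without WT 1 and -4.28 without WT 2. The cause was not tested. With an overlap of at least 50% of the shorter peak, the list outside the random range was innate lymphoid and NK (97.9) in place of dendritic genes (97.0). Lists outside the range numbered 0 to 2 with libraries left out and 2 with regions assigned to the nearest gene within 100 kb. Toward ΔEPE3, T lineage (2.02) and receptor and Notch signalling genes (2.23) left the range without WT 1. Innate lymphoid and NK genes (1.51) left it on that side without WT 2, and erythroid and mast cell genes (0.575) with the nearest gene. With libraries left out, innate lymphoid and NK genes ran from percentile 1.51 (without WT 2) to 74.3, and dendritic genes from 25.3 (without ΔEPE3 2) to 96.9. Genes past the limma threshold numbered 0 under other scalings, pseudocounts, filters, peak numbers, the widest peaks and a 50 kb extension, 51 with no extension (of the named genes only Krt5), and 0 to 405 with libraries left out; windows numbered 0 to 1569 with libraries left out. Lists by called length stayed at 0 in every alternative run. The motif search was not run, for want of a genome sequence here. Unknown depth limits every count.

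Libraries of the same number did not deviate together (correlation across genes -0.356, across windows -0.574), and the labels tie no number to an animal or day. With the replicate block, 0 genes, 4 windows and 0 lists passed. A crossed block, WT 1 with ΔEPE3 2 and WT 2 with ΔEPE3 1, chosen after seeing the data, gave 176 genes, 0 windows and 0 lists.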

Other observations

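The tests of explanations in this part were chosen after the results were seen; the setting with equal numbers of the widest peaks and the fit over windows were planned. The division of WT 1 and ΔEPE3 2 from WT 2 and ΔEPE3 1 was the largest structure in these lists. Of the regions called in WT 1 and ΔEPE3 2 only, 24.0% lay more than 100 kb from a protein-coding gene, against 8.78% of those called in WT 2 and ΔEPE3 1 only, and genes of T lineage specification held 6 of the former where matched lists gave a median of 23. For these regions every other list lay inside the random range, from percentile 6.8 (cell cycle) to 81.85 (B cell), with housekeeping genes at 37.1. Only T lineage genes thus left the range, at percentile 0.035, and their low count does not single out background. The share far from genes can follow from more background from closed chromatin in WT 1 and ΔEPE3 2, an explanation found and tested on the same lists. Greater depth of those libraries alone would leave the other pair few regions of its own, and that pair had 7644. Cells of another type could also divide the libraries: the 6 lists for B, myeloid, innate lymphoid and NK, dendritic, erythroid and mast, and stromal cells lay together at percentile 37.6, which does not decide it, since many of their regions were called in every library. Of single lists, innate lymphoid and NK genes moved with this division, with 17 regions in WT 2 and ΔEPE3 1 only against a median of 8 (percentile 99.1), so cells of that kind in those libraries stay open. The labels give no batch.

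For the larger number of peaks in ΔEPE3, depth cannot be told apart from genotype, because no depth was analysed here. With equal numbers of the widest peaks the ratio of ΔEPE3-only to WT-only regions went from 5.25 to 1.29, but width is not a measure of strength and WT 1 keeps all its peaks in that setting. A gain at lineage genes may also add regions: the genes of all 13 lists together had 150 ΔEPE3-only and 31 WT-only regions, at percentile 30.9 among matched genes, inside the random range, so that no excess at these genes was detectable.

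In a window on chromosome 11 from 52500001 to 52600000, on the high-coordinate side of Tcf7, called length was 4.26 and 5.28 kb in WT and 12.4 and 11.05 kb in ΔEPE3, a log2 difference of 1.05 ± 0.18 (SE) with a limma adjusted p of 0.930; it was picked out from the 20857 windows after its values were seen. The barcode lists overlapped between libraries 1.02 to 1.03 times as often as independent lists would.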
